A study of Chlamydomonas reinhardtii with 31 samples.

How the data were processed

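Samples were RNA of Chlamydomonas reinhardtii cultures sampled after transfer to medium without ammonium, per the labels' protocols. The 31 samples were placed in groups by the strain and time in the labels, and in library sets by the code in the titles. The 16 samples of the first set each had a pair of deposited columns and the 15 samples of the second set had 1 column each. Paired columns were treated as repeat runs of 1 sample and averaged, since their names match 1 sample; whether they are separate cultures is not given in the sources used here. Pearson's r across genes between paired columns ran from 0.937 (CC-4349 at 4 h) to 0.991. In sta6, 4159 of 14630 genes (28.4%) differed in the same direction between paired columns at all 8 times, against 0.781% from random signs. Of these, 204 differed by more than 1 (log2) on average. In CC-4349 the count was 208 (1.42%), with 0 above 1. The paired sta6 columns thus differed systematically, and averaging may not remove this from first-set contrasts of the strains. Because no source ties samples of a strain to separate cultures, p-values measure the spread between these samples, part of which may be technical.

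The deposited values were taken as FPKM, a read number divided by gene length and sequencing depth. No header names the unit, and RPKM cannot be told apart from FPKM by the values. Bowtie is named per the submitters' processing notes; its version, the genome build, annotation, counter and filters are not given in the sources used here. Depth per sample is likewise not given. Low genes carry whole multiples of the value of 1 read, and this value was recovered per gene in 3 groups of columns: first-set CC-4349, first-set sta6 and the second set. A gene was used where its low values, up to 6 times the smallest, were whole multiples of it within a tolerance of 0.02 of the multiple, with the smallest seen in at least 2 columns and a higher multiple seen. A first version of this step failed on simulated data because it mistook 1 read for a multiple in shallow columns, and it was replaced after its inconclusive slope on the difference between the library sets had been seen; the bounds set for that slope were not changed. The version used recovered 99.9% of simulated ratios within 0.01. A further check, added after seeing the data, asked per column which share of low values were whole multiples of the value of 1 read in sta6 and rescued columns; on simulated data this share was 100% with the same value per gene and at most 13.9% with different ones.

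Tests used log2(FPKM + 1) and limma 3.58.1 in R 4.3.3 with trend and robust fitting, on genes of at least 1 FPKM in at least 3 fitted libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The choice of limma followed from the unit, as fixed before the data were examined. Fold changes on this scale understate changes of low genes. Times were compared with 0 h in the first set with strain and time as factors (7 residual degrees of freedom). The comparison of sta6 with CC-4349 used 22 libraries with a block for each of 11 time-and-set pairs. Class contrasts used the 15 libraries of the second set with time and class, and the contrasts at each time used 1 mean per class and time (6 residual degrees of freedom). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the other steps.

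The model fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. At a change of 1, limma recovered 17% of seeded genes in the 2 h contrast, 75% in sta6 against CC-4349, 84% in sta6 against rescued strains, 69% in the contrast at 0.5 h and 40% in the difference of responses. At a change of 2 these shares were 70%, 97%, 100%, 96% and 89%. Genes called without a seeded change made up between 2.9% and 9.8% of calls. The simulated noise was independent between libraries, with no link between samples of a strain. Changes were seeded only in genes above the median level. So these shares may not hold for the reported calls.

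Named genes were to be the largest rises and falls among genes that passed, had a symbol, lay above the median level and moved the same way in the required pairs or strains. Neither the files nor the reference table of the Chlamydomonas_reinhardtii_v5.5 assembly gave a symbol for these IDs, so the symbol condition was dropped and the first 2 rises and 2 falls were printed for each comparison; the difference of responses had no level or direction condition. Gene lists written before the data were examined rest on symbols and were not tested here, and the STA6 gene could not be looked up by name. Of 17301 IDs, 12666 (73.2%) matched a locus tag of that assembly, which was used only for which genes neighbour each other.

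Alternatives fixed before the data were examined were quantile normalization, no filter on low values, limma without trend and robust fitting, pseudocounts of 0.1 and 5, other sets of samples, other blocks, and leaving out strains or times. Equal medians, the first run only and fits without doubted libraries were added after seeing the data.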

Results

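RNA sequencing measured transcripts of the green alga Chlamydomonas reinhardtii after cells were moved to medium without nitrogen. The first library set held CC-4349, labelled wild type, and sta6 (CC-4348), a mutant unable to make starch, each at 0, 0.5, 2, 4, 8, 12, 24 and 48 h. The second set held both strains and 3 independent strains called rescued strains here (STA6-C2, STA6-C4, STA6-C6) at 0.5, 4 and 48 h. There were 31 samples, 16 in the first set and 15 in the second, with 1 sample per strain, time and set, so strain-and-time groups had no replicates within a set. The deposited table listed 17301 genes. FPKM sums ran from 552025 to 889042 per column, and between 5.68% and 11.5% of genes were listed at 0. Total read counts per sample are not given in the sources used here. Genes are named by the IDs in the table, since the files do not pair these IDs with gene names.

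The gene Cre03.g188250.t1.1 separated sta6 from every other strain. It ranged from 0.478 to 2.55 FPKM in the 11 sta6 libraries, with a mean of 1.096 ± 0.627 (SD, n = 11). In CC-4349 it ranged from 98.2 to 503 FPKM, with a mean of 234 ± 127 (SD, n = 11). Its mean was 535 ± 282 FPKM in STA6-C2, 226 ± 105 in STA6-C4 and 237 ± 100 in STA6-C6 (SD over 3 times each). It was the 1 gene in the table whose highest sta6 value lay below the lowest value of all other libraries by more than 10 times, with the other libraries at 1 FPKM or more. This criterion was chosen after its values were seen. The neighbouring gene Cre03.g188300.t1.2, by gene order in the Chlamydomonas_reinhardtii_v5.5 assembly, lay between 4.21 and 8.96 FPKM in CC-4349. It reached at most 0.0892 FPKM in sta6 and 0.0415 FPKM in the rescued strains.

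**Figure D1:**
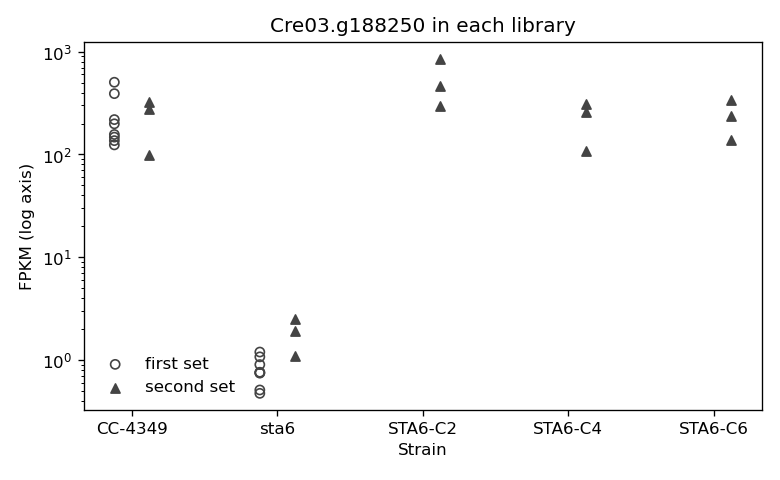
FPKM of Cre03.g188250 on a log axis in each library, by strain, with open circles for the first set and filled triangles for the second. The sta6 libraries lie between 0.478 and 2.55 FPKM and all other libraries at 98.2 FPKM or more.

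The CC-4349 columns of the first set differed from all other columns in how much FPKM 1 read was worth, gene by gene. This value could be recovered for low genes, whose FPKM are whole multiples of it. It matched between first-set sta6 and the second set within 0.01 (log2) for 99.3% of 725 genes, once the overall ratio was set to 0. Between first-set CC-4349 and first-set sta6 it matched for 6.25% of 704 genes, and between first-set CC-4349 and the second set for 5.34% of 599 genes. The log2 ratio of first-set CC-4349 to first-set sta6 exceeded 0.2 for 25.7% of genes. For 95% of these genes the ratio lay between -0.0834 and 0.813, and it was not measured for higher genes. First-set differences between sta6 and CC-4349 of this size cannot be told apart from quantification, whereas the second set did not show it. Some larger differences recurred in the second set: Cre06.g299550.t1.1 had a log2 fold change of 4.64 in the first set alone and 5.33 in the second, and Cre03.g188250.t1.1 had -6.86 and -6.21. Against the value of 1 read in sta6 and rescued columns, between 99.8% and 100% of the low values of second-set CC-4349 were whole multiples within 0.01 (log2), and between 21.4% and 29.0% of those of first-set CC-4349. Comparisons of times within a strain are not affected by a constant factor per gene, except through the pseudocount.

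**Figure D2:**
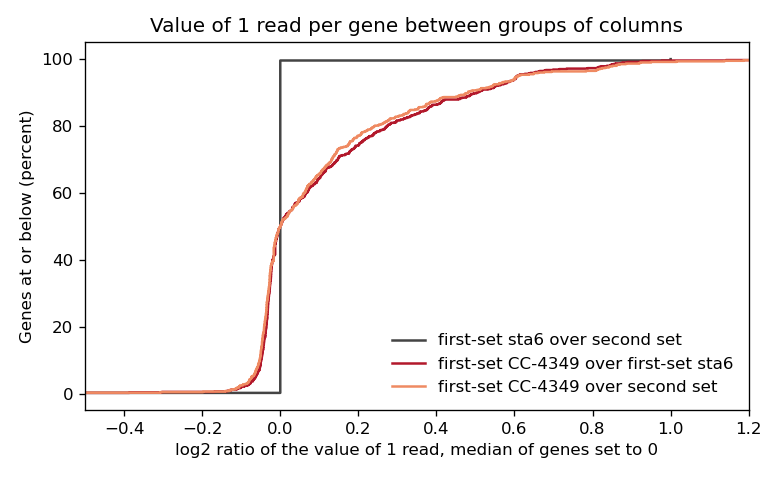
Cumulative percent of low genes (vertical axis) against the log2 ratio of the FPKM value of 1 read between groups of columns, with the median of genes set to 0 (horizontal axis). First-set sta6 and the second set match within 0.01 for 99.3% of genes, first-set CC-4349 and first-set sta6 for 6.25%.

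The first set asked which transcripts changed after nitrogen was removed. At 2 h, Cre13.g569850.t1.1 rose from 11.5 to 1368 FPKM in CC-4349 and from 2.35 to 2226 FPKM in sta6. Cre12.g551300.t1.1 rose from 1.04 to 2231 FPKM in CC-4349 and from 1.71 to 124 FPKM in sta6. Cre03.g173100.t1.1 fell from 205 to 0.533 FPKM in CC-4349 and from 160 to 0.980 FPKM in sta6, and Cre06.g296700.t1.1 from 153 to 0.278 FPKM and from 173 to 4.80 FPKM. Their fitted log2 fold changes, on the log2(FPKM + 1) scale, were 8.08 ± 0.802 (SE), 7.81 ± 0.877, -6.71 ± 1.36 and -5.91 ± 0.597, with limma adjusted p of 0.000168, 0.000246, 0.00290 and 0.000175. Among 15108 genes tested with limma, 6017 were higher and 2223 lower at 2 h than at 0 h. This split depended on the scaling. With quantile normalization 3375 were higher and 2966 lower, and with equal medians, an alternative chosen after seeing the data, 3079 and 3297. Both alternatives force the libraries to match, so they cannot tell a shift from scaling apart from a shift in the transcripts. The median log2 fold change of all tested genes was 0.53 as deposited and 0.12 after quantile normalization.

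At 48 h, Cre12.g548950.t1.1 had fallen from 10225 to 1.18 FPKM in CC-4349 and from 8273 to 31.7 FPKM in sta6. Cre31.g780700.t1.2 fell from 496 to 0.634 FPKM in CC-4349 and from 451 to 0.356 FPKM in sta6. Cre03.g159250.t1.2 was listed at 0 in CC-4349 at 0 h and reached 351 FPKM at 48 h, and rose from 0.876 to 363 FPKM in sta6. Cre10.g448450.t1.2 rose from 0.0590 to 738 FPKM in CC-4349 and from 0.0480 to 96.2 FPKM in sta6. Fitted log2 fold changes were -10.09 ± 1.21 (SE), -8.32 ± 0.479, 8.03 ± 0.768 and 7.99 ± 1.41, with limma adjusted p of 0.000244, 5.83e-06, 9.30e-05 and 0.00158. There were 5720 genes higher and 1786 lower than at 0 h. Quantile normalization gave 2929 and 2610, and equal medians 2628 and 3295. The median log2 fold change of all tested genes was 0.52 as deposited and 0.07 after quantile normalization.

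At 0.5 h 2237 genes were higher and 924 lower than at 0 h. This count includes the sta6 library at 0.5 h, which lay near its own 0 h library: 2744 of 15108 genes differed by more than 1 (log2) from 0 h, against 6521 in CC-4349. The count therefore does not show a small early response. Between 4 and 24 h the higher genes numbered 5587 to 5824 and the lower genes 1499 to 1789. At both 2 and 48 h 4025 genes were higher and 1162 lower. Another 1958 genes were higher at 2 h without a call at 48 h, and 1566 were higher at 48 h without a call at 2 h. At all 7 times 1517 genes were higher and 321 lower than at 0 h, and 3874 were called at no time. The 0 h reference was 1 sample per strain and was shared by all 7 times, so its noise alone can place a gene on several of these lists. The residual of this fit held the differences between the strains as well as noise.

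**Figure D3:**
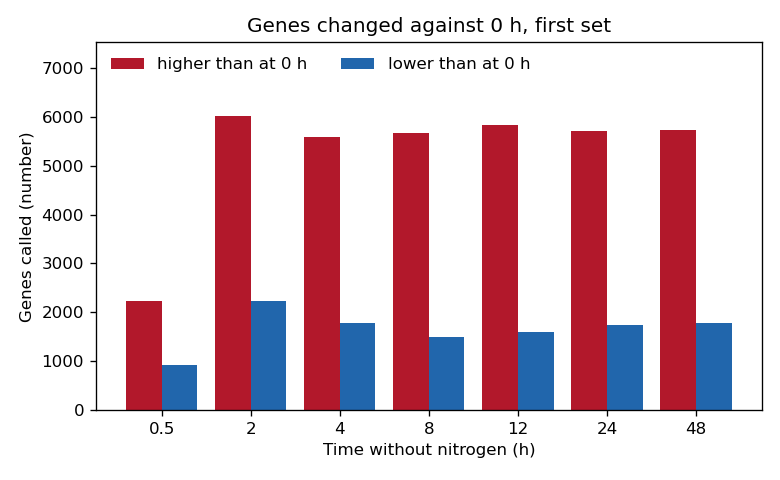
Number of genes called higher (red) or lower (blue) than at 0 h (vertical axis) at each time without nitrogen in hours (horizontal axis), from CC-4349 and sta6 of the first set. Higher genes increase from 2237 at 0.5 h to 6017 at 2 h, but the sta6 library at 0.5 h lay near its own 0 h library, and the split between higher and lower depends on the authors' scaling.

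Mutant and wild-type-labelled strains were compared over 11 pairs of the same time and set. Cre06.g299550.t1.1 was higher in sta6 in 11 of 11 pairs, at 37.9 ± 9.42 FPKM (SD, n = 8) in the first set and 54.1 ± 18.6 (SD, n = 3) in the second, against 0.549 ± 0.255 and 0.310 ± 0.0834 FPKM in CC-4349. Its fitted log2 fold change was 4.82 ± 0.149 (SE; limma adjusted p = 8.05e-11). Cre03.g188250.t1.1 was lower in 11 of 11 pairs (log2 fold change -6.68 ± 0.237, limma adjusted p = 3.37e-10). Cre04.g223100.t1.1 was lower in 11 of 11 pairs (-6.47 ± 0.707, limma adjusted p = 4.08e-05), but did not pass in the second set alone (-3.81, limma adjusted p = 0.113). Cre04.g219250.t1.1 was higher in 9 of 11 pairs (4.45 ± 0.834, limma adjusted p = 0.00213); it was listed at 0 in every first-set CC-4349 library, lay between 61.3 and 81.2 FPKM in second-set CC-4349, and its difference turned to -0.33 in the second set alone (limma adjusted p = 0.655). Of 15326 genes tested, limma called 1097 higher and 3462 lower in sta6, or 553 and 1513 with no replicate block. In the second set alone, where the value of 1 read was shared, it called 275 higher and 605 lower. Of these genes 464 were also called in both sets together, a fit that holds the same second-set libraries. The fits of each set alone share no library. Between them 103 genes were higher in both, where independent lists would share 24.4. Another 255 were lower in both, with 172 from independent lists, and 84 went opposite ways. Quantile normalization of both sets gave 1746 higher and 1669 lower, and equal medians 2308 and 1317. The median log2 fold change of all tested genes was -0.18 as deposited, -0.02 after quantile normalization and 0.01 in the second set alone. Of the 11 pairs, 8 came from the first set, in which the quantification differed between the strains.

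The library sets correlated more closely for sta6 than for CC-4349. First-set sta6 correlated best with its own group among the 15 second-set libraries at each shared time, with Pearson's r across genes of 0.889 at 0.5 h, 0.971 at 4 h and 0.948 at 48 h. First-set CC-4349 correlated with second-set CC-4349 at 0.857, 0.870 and 0.879, below every other second-set library of the same time, of which the lowest values were 0.913, 0.906 and 0.891. Genes are not independent replicates in these correlations. Across genes, the sta6 minus CC-4349 difference of the first set correlated with that of the second at r = 0.26. In the 12 libraries of the shared times, limma found 281 genes whose difference between the strains differed between the sets. Some of these involve a change in sta6 itself. Cre15.g637600.t1.1 and Cre15.g637650.t1.1 (-8.91 and -8.61, log2) were at most 1.13 FPKM in first-set sta6 and at least 23.5 FPKM in second-set sta6. How many of the 281 genes rest on either strain was not tested.

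Within the sta6 lineage, the contrast of sta6 with the rescued strains used the second set alone. Cre15.g637600.t1.1 lay between 23.5 and 301 FPKM in sta6 and between 0.0371 and 5.87 FPKM in the 9 rescued libraries, and Cre15.g637650.t1.1 between 26.0 and 344 FPKM in sta6 and at most 4.999 FPKM in the rescued libraries, 1 of them listed at 0. Both were at most 1.13 FPKM in first-set sta6. Cre03.g188250.t1.1 was lower in sta6 (log2 fold change -6.66 ± 0.404, limma adjusted p = 1.07e-06) and Cre04.g223100.t1.1 likewise (-3.88 ± 0.626, limma adjusted p = 0.0104), each in 9 of 9 comparisons of libraries at the same time. With 1 value per strain neither fall passed (limma adjusted p = 0.0884 and 0.198), and the latter also missed the threshold without STA6-C4 (0.0588), STA6-C6 (0.0666), the 0.5 h libraries (0.101) or the 4 h libraries (0.117), and with a pseudocount of 5 (-2.68, 0.0629). The log2 fold changes of the 2 genes that were higher were 6.01 ± 0.510 and 5.89 ± 0.596, with limma adjusted p of 3.18e-05 and 0.000191, also in 9 of 9 comparisons. Of 14982 genes tested, 53 were higher and 58 lower in sta6. The count of 111 depended on how replication was treated: it was 538 with only the 2 classes compared, 514 with 1 value per strain and 1345 with strain as a random block. Both rises still passed with 1 value per strain, but there the sta6 group held a single value. Its spread came from the rescued strains alone, so neither these rises nor the falls that missed show how sta6 varies. The split changed with scaling, to 62 higher and 38 lower with quantile normalization and 83 and 38 with equal medians. The count fell to 53 without the 0.5 h libraries and 29 without the 4 h libraries, and rose to 792 without the 48 h libraries, and leaving out STA6-C2, STA6-C4 or STA6-C6 gave 58, 46 and 57.

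Rescued strains and CC-4349 were compared in the second set. Cre17.g700750.t1.1 averaged 1058 ± 187 FPKM (SD over strains and times, n = 9) in the rescued strains and 1.54 ± 0.478 (SD, n = 3) in second-set CC-4349, although it was between 486 and 2073 FPKM in first-set CC-4349. Cre06.g299550.t1.1 averaged 66.9 ± 26.9 FPKM against 0.310 ± 0.0834. Cre01.g045200.t1.1 averaged 0.362 ± 0.248 FPKM in the rescued strains and 440 ± 275 in second-set CC-4349, although it was between 0.231 and 37.2 in first-set CC-4349. Cre38.g785200.t1.1 was at most 0.741 FPKM in the rescued strains, with 1 library listed at 0, and averaged 124 ± 37.6 FPKM in second-set CC-4349 but lay between 2.88 and 35.5 FPKM in first-set CC-4349. Log2 fold changes were 8.70 ± 0.289 (SE), 5.59 ± 0.192, -8.11 ± 0.255 and -6.53 ± 0.197, with limma adjusted p of 8.47e-11, 9.31e-11, 4.24e-11 and 2.71e-11, each in the same direction in 9 of 9 comparisons of libraries at the same time. There were 2415 genes higher and 2445 lower in the rescued strains. The count of 4860 fell to 2924 without the 0.5 h libraries and to 2044 without the 4 h libraries, and rose to 6324 with 1 value per strain and to 7635 with strain as a random block. Only 1 CC-4349 library per time stood for that strain, and no source used here ties these libraries to separate cultures.

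At each time, 1 sta6 library was set against the 3 rescued strains, so the counts describe single libraries and give no ranking of times. At 0.5 h 1200 genes were higher and 1234 lower in sta6, at 4 h 354 and 388, and at 48 h 91 and 148. Without STA6-C6, the 0.5 h count fell from 2434 to 1268 and the 4 h count from 742 to 455. Without STA6-C4, the 4 h count was 397 and the 48 h count fell from 239 to 115, and without STA6-C6 the latter was 122. At 48 h the share of calls that were higher was 38.1% as deposited, 64.1% after quantile normalization and 74.9% with equal medians; the median log2 fold change of all genes was -0.15 as deposited and -0.01 after quantile normalization. The sta6 library was assumed to vary like the rescued strains.

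The change from 0.5 to 48 h differed between sta6 and the rescued strains for 1634 genes by limma, with 544 higher and 1090 lower in sta6. The sta6 arm had 1 library per time, so the spread came from the rescued strains alone, and variation of single libraries was not separated from a difference between groups. Cre14.g617450.t1.1 went from 4.19 to 142 FPKM in sta6 and stayed between 2.56 and 7.42 FPKM in the rescued libraries (difference in log2 fold change 5.40 ± 0.392, limma adjusted p = 0.000411); first-set sta6 also rose, from 9.61 to 179 FPKM. Cre35.g784050.t1.1 went from 18.5 FPKM to being listed at 0 in sta6, while the rescued strains went from between 17.2 and 31.1 FPKM to between 72.6 and 84.9 FPKM (-6.03 ± 0.349, limma adjusted p = 6.04e-05). First-set sta6 went the other way, from 40.0 to 134.5 FPKM, so this fall was not seen in the other set. Between those times first-set sta6 was listed at 0 at 2 h, 78.7 FPKM at 4 h and 5.46 FPKM at 8 h. Second-set sta6 was also listed at 0 at 4 h. Single values of this gene thus varied widely, and whether they rest on few reads was not tested. Cre12.g555700.t1.2 stayed at 0.177 and 0.173 FPKM in sta6 and reached 28.6, 71.2 and 108 FPKM in the rescued strains at 48 h (-5.91 ± 1.03, limma adjusted p = 0.0198, and 0.0708 without STA6-C4 or 0.0514 without STA6-C6). Cre05.g232400.t1.1 had the largest fitted rise (5.79 ± 0.488), but was listed at 0 in sta6 at both times. It lay between 35.8 and 85.8 FPKM in the rescued strains at 0.5 h and was listed at 0 in them at 48 h. At 4 h the order was reversed, with 194 FPKM in second-set sta6 and 0 in every rescued strain. In first-set sta6 it was listed at 0 in 7 of 8 libraries and at 51.6 FPKM in the other, so its values were sporadic. Quantile normalization gave 648 higher and 420 lower, equal medians 900 and 428, and the count was 833 without STA6-C2 and 263 without STA6-C6. The median of all genes was -0.18 as deposited and -0.02 after quantile normalization. In second-set CC-4349 Cre14.g617450.t1.1 also rose, from 5.88 to 352 FPKM, while first-set CC-4349 went from 117 to 109 FPKM. Cre35.g784050.t1.1 was listed at 0 in all 11 CC-4349 libraries. At 48 h Cre12.g555700.t1.2 was at 1.85 FPKM in second-set CC-4349 and 0.490 FPKM in the first set. Earlier, first-set CC-4349 did raise this gene, to 37.3 FPKM at 8 h and 37.7 FPKM at 24 h, while first-set sta6 stayed at or below 0.162 FPKM. At the 3 times of the second set, CC-4349 thus did not share the pattern of the rescued strains for these genes. That set has no library between 4 and 48 h.

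Fits that share no library were set side by side to ask what followed STA6. Of the genes called in sta6 against CC-4349 in the first set and in sta6 against the rescued strains in the second, 20 were higher in both, with 4.58 from independent lists, and 15 lower in both, with 18.3 from independent lists. Another 18 went opposite ways, and the log2 fold changes correlated across genes at r = 0.20. With a threshold of 0.01 the higher genes were 7 with 1.35, the lower 3 with 3.41, and 6 were opposite. With 0.1 they were 36 with 9.93, 66 with 52.5, and 33 opposite. Rescued strains against CC-4349 in the second set shared 355 higher genes with the first-set contrast, with 220 from independent lists, and 770 lower genes, with 765, while 833 genes went opposite ways. At a threshold of 0.01 these were 166 with 65.9, 355 with 264, and 219 opposite; at 0.1 they were 498 with 357, 1124 with 1145, and 1393 opposite. The first of these contrasts holds the difference in quantification.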

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

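Tests in this part that were chosen only after the result was seen were the share of CC-4349-only genes, the count of genes far from every first-set library, the cover of the called genes by the slope test, the direction of genes at 0.5 h, the share of the response reached at 0.5 h, and the test of the difference between library sets; the slope on the value of 1 read and the gene length test were chosen before, and the comparison of changes between times was added after the correlations but before its own values were seen.

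The change from 0.5 to 48 h differed between sta6 and the rescued strains for 1634 genes in an interaction test with limma. The sta6 arm was 1 library per time, so the test does not separate a difference between groups from variation of single libraries, and the count was 263 without STA6-C6. No group held 4 or more samples, so no sample was tested for lying far from its group.

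The difference between sta6 and CC-4349 itself differed between the library sets for 281 genes, and second-set CC-4349 correlated less with first-set CC-4349 than the rescued libraries did. The authors' quantification may account for part of the first pattern: across 736 low genes the slope of the difference between sets on the ratio of the value of 1 read was -1.76 (95% bootstrap interval -2.43 to -1.08), steeper than a constant factor per gene alone gives, but only 21 of the 281 called genes (7.47%) had such a ratio, so its part in them stays open. A constant factor per gene is argued against as the whole cause of the second pattern, since it cancels in changes between times apart from the pseudocount. The changes of every rescued strain correlated better with those of first-set CC-4349 than those of second-set CC-4349 did. This held for all 3 pairs of times, by 0.0346 to 0.234. Second-set sta6 also correlated better from 0.5 to 4 h and from 0.5 to 48 h, but not from 4 to 48 h (0.515 against 0.591). Each value rests on 1 library per strain, time and set. A sta6-lineage library under the CC-4349 label is argued against, because 83.3% of 12 genes present in first-set CC-4349 and silent in that lineage were above 1 FPKM in all second-set CC-4349 libraries. A different strain or subline under that label in either set may account for it: 33 genes of second-set CC-4349 lay more than 10 times below or above all 16 first-set libraries, against 4 of second-set sta6, which like CC-4349 has 8 libraries of its own label there, while gene length stays open because only 75.7% of genes had a length (Spearman's rho -0.0390).

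In the first set, sta6 at 0.5 h lay near its own 0 h library. Its slope on the 0 h to 2 h response of CC-4349 was 9.45%, against 76.3% for CC-4349 on that of sta6. Of 346 genes that rose by more than 3 (log2) from 0 to 2 h in CC-4349, 100 were higher in sta6 at 0.5 h than at 0 h by more than 1 in both runs and 12 were lower. Of 255 genes that fell as far, 38 were lower and 7 higher. Cre13.g569850.t1.1 went from 2.35 to 118 FPKM. These values go against a second 0 h sample under the 0.5 h label, but no repeat 0 h culture shows how far such samples differ, so it stays open. A slower response of sta6 may also account for it. The second set has no 0 h library, so those of the first set were used, that of sta6 for the sta6 lineage. The share reached at 0.5 h was taken as the slope on the first-set CC-4349 response. It was 56.9% for sta6 and 62.8% to 69.7% for the rescued strains, so sta6 lay below their range but by less than its width. The slopes were little higher at 4 h, at 0.687 for sta6 and 0.636 to 0.670 for the rescued strains. Relative to the 4 h slope of the same strain, sta6 was at 82.8% at 0.5 h and the rescued strains at 93.8% to 110%. The 56.9% of second-set sta6 was also well above the 9.45% of the first set (13.2% of its 4 h slope). So a lag of that size did not recur in this 1 library. Second-set CC-4349 had a slope of 62.0% on the sta6 response (104% of its 4 h slope), from a 0 h library that was quantified differently. These explanations cannot be told apart with 1 sta6 sample per time and set.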

How the results depend on the processing

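Of the counts of genes under other settings, 85 stayed within 1.5 times the reported count and 24 moved further; of the named genes' values, 303 kept direction and call, 10 kept direction without passing and 1 reversed. The cause was not tested except where stated. Equal medians, the first run only and fits without doubted libraries were chosen after seeing the data. For sta6 against CC-4349 the count was 880 in the second set alone, which has fewer pairs and shares the value of 1 read, and 2066 with no replicate block; Cre04.g219250.t1.1 reversed to -0.33 in the second set alone. For sta6 against rescued strains it was 538 with only the 2 classes compared, 514 with 1 value per strain and 1345 with strain as a random block, and leaving out strains or times gave 29 to 792. For rescued strains against CC-4349 it was 7635 with strain as a random block, and leaving out strains or times gave 2044 to 6110. Leaving out 1 rescued strain gave 1268 to 1777 at 0.5 h, 397 to 504 at 4 h, 115 to 181 at 48 h, and 263 to 1156 for the difference of responses, which was 1068 with quantile normalization. Genes shared in direction between the fits without shared libraries numbered 35, or 10 at a threshold of 0.01 and 102 at 0.1. Gene list tests and the STA6 level by name were not run, because no source used here gives symbols for the IDs, and other times were not left out of the 2 h and 48 h contrasts. Depth per sample is unknown, so no limit of detection is given.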

Other observations

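Tests in this part were chosen after the results were seen, except the tests on other splits of the libraries and the comparison of neighbour correlations; keeping strains whole in the splits was decided after splits that also mixed strains had been seen.

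Some genes were near or at 0 in all libraries of a strain, or of a strain in 1 set. In all 11 CC-4349 libraries 10 genes were at 1 FPKM or more while no sta6 or rescued library exceeded 0.5 FPKM, among them Cre03.g168100.t1.1, Cre03.g168150.t1.1 and Cre03.g168200.t1.1. First-set CC-4349, whose quantification differed, lay more than 10 times below every other library for 13 genes, 8 of them listed at 0 in all 8 libraries, and 9 of the 13 carry IDs from Cre04.g219000.t1.1 to Cre04.g219650.t1.1. Second-set CC-4349 did so for 10 other genes, among them Cre01.g014650.t1.1 (at most 0.0673 FPKM against at least 16.4 FPKM elsewhere), and lay above 10 times every other library for 18 genes, among them Cre16.g654050.t1.1 (at least 32.9 FPKM and listed at 0 elsewhere).

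Within the sta6 lineage of the second set, each strain had genes set apart from the other lineage strains by at least 1 (log2) at all 3 times. There were 10 in sta6, 3 in STA6-C2, 7 in STA6-C4 and 7 in STA6-C6. Of the sta6 genes, Cre03.g188250.t1.1 was low in sta6 of both sets. Cre23.g765800.t1.2 was at most 0.124 FPKM in second-set sta6 but at least 3.49 FPKM in every other library, first-set sta6 included. Cre15.g637600.t1.1 and Cre15.g637650.t1.1 were high in second-set sta6 but at most 1.13 FPKM in first-set sta6. So part of the sta6 count describes sta6 of 1 set rather than the strain. The fewest in any strain was 3, and the most in any of 60 mixed sets of libraries was 1. So such differences recurred across the times of a strain within the second set. The mixed sets broke up the libraries of a strain, which belong together, so they cannot decide on chance choice of libraries, which stays open. In STA6-C4, Cre05.g236050.t1.2 and Cre05.g236100.t1.2 reached at most 0.0121 and 0.0366 FPKM, against at least 1.94 and 2.95 FPKM in the other lineage strains.

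A hypothesis for Cre03.g188250.t1.1 is that the gene is the STA6 locus, lost in sta6 and put back in the rescued strains. The test counted genes whose highest sta6 value lay more than 10 times below the lowest value elsewhere, and 1 gene did. That count follows from the pattern that led to the hypothesis, and no source used here pairs the gene with a name, so the hypothesis stays open and may be wrong.

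The libraries of a strain within a set belong together, so only splits that keep them whole were counted. They are 2 for sta6 against CC-4349 and 4 for each contrast of the second set, too few for a share under 0.05. The real values were 4559 in sta6 against CC-4349 (highest other 2737), 111 in sta6 against rescued strains (highest other 20) and 4860 in rescued strains against CC-4349 (highest other 12), each reached by 1 split, the real one.

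Genes called between sta6 and CC-4349 often neighboured each other: 629 lay in runs of at least 3 neighbours called the same way, against at most 426 in 1000 random orders. The correlation of neighbours was 0.0814 higher than in the 48 h contrast. Only 72.6% of the called genes matched the gene order, under the minimum of 80%, so both values describe the matched genes, and both tests are void for the called genes as a whole.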
